A study of Mus musculus with 160 samples.

How the data were processed

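RNA was measured in 160 libraries from 32 mice, 1 library per mouse in each of cortex, striatum, tibialis muscle, heart and liver. Per the labels, the mice were wild type or R6/2 on a C57BL/6J background and were dosed by mouth 2 times a day with vehicle or, in R6/2 only, with CHDI-00390576 at 30 or 100 mg/kg. No wild-type mice received the drug. Each tissue has 4 arms of 8 mice, with 4 males and 4 females in each. Per the labels' protocols, frozen tissue gave total RNA by the miRNeasy kit, RNA integrity was checked on a Bioanalyzer, at least 3.75 µg went into each library, and libraries followed a standard Illumina protocol. CASAVA 1.8.2 is the only tool per the submitters' processing notes; the aligner, the quantifier, the genome build and the annotation are not given in the sources used here.

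The deposited tables hold, per the file headers, 1 column per library and 43432 Ensembl mouse genes. The first deposited unit is the expected count, an estimated number of reads per gene that the authors did not scale to depth or length; 67.7% of the values above 0 were whole numbers. The second deposited unit is FPKM, fragments scaled to transcript length and library size, which the authors gave for the same libraries. Every value column was used, so unused columns number 0. Symbols for 42462 genes came from GENCODE M21 on GRCm38 by gene identifier. Totals per library, in M counts, ran from 30.3 to 35.5 in cortex (median 33.3), 30.1 to 38.9 in striatum (32.45), 33.4 to 39 in tibialis (35.85), 33.7 to 38.6 in heart (36) and 31.5 to 37.2 in liver (33.9). The 10 most abundant genes took 8.6%, 10.2%, 22.5%, 31.3% and 18.7% of counts in the same order. The spread between mice, not counting error alone, sets the errors given.

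Each tissue was fitted alone on its 32 libraries in R 4.3.3 with edgeR 4.0.16. Expected counts were rounded, genes with low counts were removed with filterByExpr by arm, libraries were scaled with TMM, and a quasi-likelihood model with arm and sex (estimateDisp, glmQLFit, glmQLFTest) gave log2 fold changes. The SE is the absolute log2 fold change over the square root of F. Benjamini-Hochberg adjusted p under 0.05 counted as past the test. The filter left 17508, 17428, 15760, 15812 and 14931 genes. The comparisons were R6/2 vehicle against wild type, each dose against R6/2 vehicle, 100 against 30 mg/kg, and the sex differences (males minus females) in the genotype effect and in the 100 mg/kg effect, from a fit of 8 means for arm and sex. The fit was tested on simulated data made from these libraries, with 100 genes changed by 0.5 and 100 by 1. The changed genes were drawn from those with a mean log2 CPM of at least 1, and simulated genes varied independently. The 100 mg/kg comparison recovered 88% and 99% in cortex, 73% and 93% in striatum and 71% and 98% in tibialis. In heart it recovered 80% and 97% and in liver 63% and 89%. There were 6 to 9 wrong calls per tissue and 0 calls in an unchanged comparison.

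The genes named in the text follow a rule. For each tissue and for R6/2 against wild type and each dose against vehicle, these are, among genes past the test with a mean log2 CPM of at least 1 and the same sign in both sexes, the 5 largest and 5 smallest log2 fold changes, passing over predicted genes. Where no gene passed, the gene with the smallest p is named as not passing. Sex differences name up to 3 genes past the test with the smallest p. Each gene list past camera names up to 4 members with the smallest p. Genes past the test in the same direction in all 5 tissues are named up to 10, by mean change. Htt, Gm12695, Hdac4, Hdac5, Hdac7, Hdac9, Mef2a, Mef2c, Mef2d, Xist and Ddx3y are always open to naming. Genes named outside the rule are said to be so.

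The 46 gene lists for tissue, cell type, treatment and pathway were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with at least 5 members tested, and again with an estimated correlation, each adjusted over the lists of a tissue and comparison (25 or 26). Of the list symbols 4 were not found and 3 were matched by a newer name. The disease index of a mouse is the slope, through 0, of its profile relative to wild type on the R6/2 profile over 300 genes picked by limma; 36 splits of the 8 vehicle mice, balanced by sex, kept each vehicle mouse out of the genes and profile it was scored on. Doses were compared with vehicle by a two-sided exact permutation test within sex over 4900 assignments, adjusted over 10 tests. The covariance of the effects of the doses used the same 36 splits and 20 simulations.

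The alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma-trend on log2 FPKM with a pseudocount of 0.1 and a minimum mean of 0.5, the replicate number as a block, the 2 compared groups fitted alone, the index with 100 or 1000 genes or on FPKM values, and camera with an estimated correlation. Fits added after the data were seen left out 14 libraries of few long transcripts or 2 libraries whose sex genes contradict the label. Further ones took the form of the library name as a covariate in cortex and liver, since 22 of the 160 libraries carry a second form. Libraries of few long transcripts had a slope on transcript length under -0.1, a threshold chosen after seeing the slopes. The slope was that of a library's expression relative to the median of its arm. A shift shared by a whole arm therefore cannot show in it, and these fits do not address one. Libraries of few long transcripts number 3 in cortex (1 on vehicle, 2 at 100 mg/kg), 4 in striatum (1 on vehicle, 3 at 100 mg/kg), 2 in tibialis (1 wild type, 1 at 100 mg/kg), 2 in heart (1 wild type, 1 at 100 mg/kg) and 3 in liver (1 on vehicle, 1 each at 30 and 100 mg/kg). A few single genes past these rules are not reported here, and the comparisons of named genes leave them out. No library was left out of the values given unless the text says so, and the tables were read with the data.table package, version 1.17.8.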

Results

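R6/2 mice, a transgenic model of Huntington's disease, carried an expression signature in each of the 5 tissues studied. Many genes changed in opposite directions in different tissues, a number that was not set against chance. In R6/2 mice given oral CHDI-00390576, named in the series title as an inhibitor of class IIa histone deacetylases, at 100 mg/kg, 308 genes differed from vehicle in liver and at most 2 in any other tissue by the main edgeR fit, while other settings gave up to 60 in heart and 15 in cortex. The series holds 160 RNA libraries from 32 mice, 1 library each from cortex, striatum, tibialis muscle, heart and liver. Each tissue has 8 wild-type mice on vehicle, 8 R6/2 mice on vehicle and 8 R6/2 mice at each of 30 and 100 mg/kg, with 4 males and 4 females per arm. Levels are counts-per-million (CPM) ± SD over 8 mice, and changes are log2 fold changes ± SE with n = 8 per arm, unless other numbers are given. A gene rose or fell where its adjusted p from edgeR was under 0.05. The rule for named genes ranks only those with a mean log2 CPM of at least 1 and the same sign in both sexes, and passes over predicted genes, so larger changes exist outside it. Member counts of gene lists were the same when adjusted over the list alone unless a second count is given.

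Gm12695 (ENSMUSG00000078639; chromosome 4, 96723647 to 96785186 in GRCm38, protein coding), the gene in which the R6/2 transgene is known to have inserted, separated the genotypes in every tissue. It stood at 3.2 ± 0.317 CPM in R6/2 vehicle cortex against 0.0561 ± 0.0336 in wild type, a change of 5.75 ± 0.19. In heart it stood at 1.99 ± 0.235 against 0.0347 CPM, and in liver at 3.2 ± 0.834 against 0.00406 CPM. Htt (ENSMUSG00000029104; chromosome 5, 34761740 to 34912534), the mouse huntingtin gene, was at 221 ± 26.8 CPM in R6/2 cortex and 220 ± 15.6 in wild type. It passed the test only in liver (-0.38 ± 0.11, adjusted p = 0.0192). There it was at 39.5 ± 1.36 CPM in wild type and 30.3 ± 6.05 in R6/2 vehicle. The R6/2 mice at 30 and 100 mg/kg, at 36.9 ± 4.31 and 36.8 ± 5.88 CPM, lay nearer wild type, with which they were not compared. That liver call was lost on FPKM values (-0.35, adjusted p = 0.0785), the highest over 8 alternatives, which started at 0.00308. Xist, the RNA of the inactive X chromosome, and Ddx3y, a Y-linked gene, contradicted the sex label in 2 brain libraries of 1 wild-type female, as detailed among the closing observations.

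In cortex, transcripts of neuronal channels and cell type markers fell in R6/2 mice, and interferon response and developmental genes rose. The lists of the last 2 kinds did not hold with an estimated correlation (adjusted p = 0.0689 and 0.0576). Of the cell type lists past camera, only that of interneurons held with it. Scn4b, a sodium channel subunit, fell from 145 ± 31.3 to 16 ± 1.08 CPM (-3.18 ± 0.11, adjusted p = 1.81e-20), and Kcnh4, a potassium channel, fell from 24.5 ± 2.13 to 3.59 ± 0.46 CPM (-2.77 ± 0.09). Plk5 (-3.16), Adam33 (-2.8), a metalloprotease, and Ryr1 (-2.58 ± 0.12), a calcium release channel, completed the 5 steepest falls under the rule for named genes. The 5 largest rises under it were Rgs13, a regulator of G protein signalling (3.75 ± 0.643 against 0.363 ± 0.102 CPM, 3.36 ± 0.15), the interferon regulator Irf7 (2.28 ± 0.1), Ifi44 (2.23), the transcription factor Onecut2 (22.3 ± 3.3 against 5.41 ± 1.19 CPM, 2.05 ± 0.12) and Oasl2 (2.01 ± 0.11). For Rgs13, Irf7, Onecut2, Scn4b and Kcnh4, all 8 R6/2 mice lay outside the range of the 8 wild-type mice. In total 4921 genes rose and 4518 fell, 53.9% of the 17508 tested, and 778 changed by more than 1 on the log2 scale. On FPKM values the split was 6442 higher and 2901 lower.

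Markers of several cortical cell types fell together, although with an estimated correlation only the interneuron list among them held. Among 15 interneuron markers 13 fell (camera adjusted p = 2.15e-06, and 0.0123 with an estimated correlation). The neuropeptide gene Vip fell from 38.1 ± 3.06 to 13.7 ± 0.935 CPM, and the neuropeptide genes Npy and Sst stood at -1.17 ± 0.09 and -1.16 ± 0.09. Voltage-gated potassium channel genes showed 20 falls and 1 rise among 23 (21 falls when adjusted over the list alone; camera adjusted p = 1.12e-10, and 0.0133 with an estimated correlation). Kcnh3 stood at -1.43 and Kcnip2 at -1.35. Circadian clock genes showed 16 falls and 1 rise among 19, with Bhlhe40 at -1.42, Hlf at -0.88 and Npas2 at -0.83 (camera adjusted p = 1.13e-07, and 0.0123 with an estimated correlation). Genes of striatal projection neurons, also expressed in cortex, fell in 33 of 39 cases, among them Itpka (-1.73) and Rasd2 (-1.56), with camera adjusted p = 4.3e-10 but adjusted p = 0.271 with an estimated correlation. Cortical glutamatergic neuron markers fell in 13 of 18 cases and rose in 2 (14 falls when adjusted over the list alone). Camk2a, a synaptic kinase, went from 3340 ± 218 to 1690 ± 76.7 CPM and Lamp5 from 218 to 47.6 CPM, and the list's adjusted p was 2.87e-06, or 0.063 with an estimated correlation. Astrocyte markers fell in 14 of 18 cases and rose in 2 (3 rises when adjusted over the list alone; adjusted p = 3.43e-05, and 0.0742 with an estimated correlation). The glutamine synthetase gene Glul stood at -0.9 and the gap junction gene Gja1 at -0.64.

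Cholesterol synthesis, immediate early and synaptic vesicle genes also fell in cortex, their lists not holding with an estimated correlation. Cholesterol synthesis genes fell in 22 of 25 cases (adjusted p = 4.7e-08, and 0.112 with an estimated correlation). Insig1, a sensor of sterols, stood at -0.64 and Fdft1, the squalene synthase gene, at -0.6. Immediate early genes fell in 14 of 25 cases, with Arc at -1.78 ± 0.25 and Dusp1 at -1.1 (adjusted p = 0.00106, and 0.616 with an estimated correlation). Synaptic vesicle genes fell in 13 of 24 cases and rose in 2, with Cplx2 at -1.09 and Vamp1 at -1.07 (adjusted p = 3.78e-05, and 0.112 with an estimated correlation). Neuronal MEF2 targets fell in 12 of 25 cases and rose in 4, with Bdnf, a neurotrophin, at -0.78 ± 0.14 (adjusted p = 0.013, and 0.616 with an estimated correlation). Glucocorticoid response genes fell in 14 of 20 cases (15 when adjusted over the list alone; adjusted p = 0.00125, and 0.37 with an estimated correlation). Cdkn1a stood at -1.42 and Zbtb16 at -1.06. Homeobox and other developmental regulators rose in 12 of 22 cases and fell in 2 (13 rises when adjusted over the list alone). Pou4f1 stood at 2.91 ± 0.734 against 0.0595 ± 0.0428 CPM and Hoxb5 at 0.628 ± 0.217 against 0 CPM, while the interneuron regulator Dlx1 fell (-0.64), and the list's adjusted p was 0.00125, or 0.0576 with an estimated correlation. Oxidative phosphorylation genes rose in 18 of 39 cases and fell in 1, by a median of 0.12 (adjusted p = 0.0079, and 0.705 with an estimated correlation). Sdha stood at 0.25 and Cox6a2 at -1.45.

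In striatum, genes of the projection neurons that make up most of this region fell, a list with adjusted p = 0.0582 with an estimated correlation. Ryr1 fell from 149 ± 15.6 to 8.24 ± 2.31 CPM (-4.17 ± 0.18, adjusted p = 2.73e-17), Scn4b from 1690 ± 202 to 163 ± 34.7 CPM (-3.38 ± 0.18) and the cannabinoid receptor gene Cnr1 from 510 ± 57.9 to 115 ± 20.4 CPM (-2.15 ± 0.1). Abi3bp (-3.45), Ptprv (-3.44) and Ptpn7 (-3.35) completed the 5 steepest falls under the rule. The largest rises under it were Zfhx2os (2.88 ± 0.28), Arhgap36 (2.54 ± 0.45), Ifi44 (2.45), AW551984 (2.37) and Usp18 (2.33), which removes the interferon-induced modifier ISG15. Of 39 striatal projection neuron genes 33 fell and 2 rose, with a median of -1.3 (camera adjusted p = 6.28e-21, but 0.0582 with an estimated correlation). Among them the adenosine receptor gene Adora2a stood at -1.97. In total 3943 genes rose and 3445 fell, 42.4% of 17428, with 1080 changed by more than 1, and FPKM values gave 5232 and 2064. The striatal vehicle library of male 2 had few long transcripts and 17.49% mitochondrial counts.

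Further gene groups fell in striatum. Potassium channel genes fell in 19 of 23 cases (20 when adjusted over the list alone; camera adjusted p = 1.71e-11, and 0.0299 with an estimated correlation). Kcnh4 stood at -2.73 and Kcnh3 at -1.74. Interneuron markers fell in 9 of 15 cases (adjusted p = 9.44e-05, and 0.00333 with an estimated correlation). Slc5a7, the choline transporter gene, stood at -1.69 and the nitric oxide synthase gene Nos1 at -1.18. Cholesterol synthesis genes fell in 17 of 25 cases, with Insig1 at -0.93 (adjusted p = 2.89e-08, and 0.0486 with an estimated correlation). Astrocyte markers fell in 12 of 18 cases and rose in 2 (13 falls when adjusted over the list alone; adjusted p = 7.38e-05, and 0.0299 with an estimated correlation). The glutamate transporter gene Slc1a2 went from 3090 ± 529 to 1410 ± 218 CPM. Clock genes fell in 16 of 19 cases and rose in 1, with Npas2 at -1.34 (adjusted p = 1.46e-07, and 0.00478 with an estimated correlation). Immediate early genes fell in 13 of 25 cases (14 when adjusted over the list alone), with Egr1 at -1.07 (list adjusted p = 0.385 with an estimated correlation). Neuronal MEF2 targets fell in 10 of 25 cases and rose in 2 (11 falls when adjusted over the list alone), and glucocorticoid response genes fell in 12 of 20 cases (13 when adjusted over the list alone), with adjusted p = 0.398 and 0.348 with an estimated correlation. Cortical glutamatergic markers fell in 5 of 18 cases, and oxidative phosphorylation genes rose in 5 of 39 (3 when adjusted over the list alone) with Sdha at 0.23. The last 2 lists had adjusted p = 0.454 and 0.767 with an estimated correlation, and all 5 of these lists passed camera with its preset one.

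**Figure D1:**
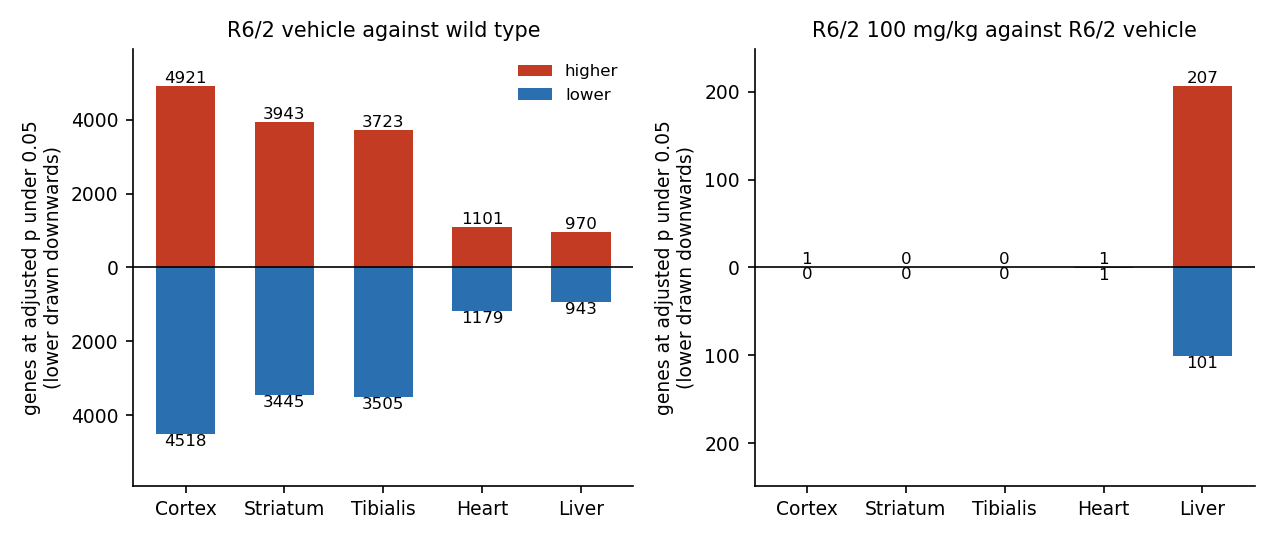
Bars give the number of genes higher and lower at adjusted p under 0.05 in each tissue, for R6/2 vehicle against wild type and for 100 mg/kg against R6/2 vehicle, with 8 mice per arm. The genotype comparison runs from 4921 higher and 4518 lower in cortex to 970 and 943 in liver, while liver alone has more than 2 genes in the drug comparison (207 and 101).

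In tibialis muscle, R6/2 mice lost fast fibre transcripts and gained genes that muscle expresses after denervation. Fam57b fell from 67.7 ± 14 to 4.02 ± 0.88 CPM (-4.07 ± 0.18, adjusted p = 1.16e-17), and the kinase gene Mylk4 fell from 2210 ± 749 to 202 ± 29.4 CPM (-3.47 ± 0.2). Cacna2d4 (-3.84), a calcium channel subunit, Mss51 (-3.6) and Adamts8 (-3.42) were the other steep falls. Sln, which inhibits the calcium pump of the sarcoplasmic reticulum, rose from 1.31 ± 0.751 to 29.8 ± 22.3 CPM (4.38 ± 0.36), followed by Prr32 (4.19), Ddc (3.44), Ano3 (3.41) and Igsf1 (3.33). All 22 fast fibre genes fell with a median of -1.79, with Aldoa at -2.01, Casq1 at -1.89 ± 0.07 and Tnnt3 at -1.79 (camera adjusted p = 4.78e-34, and 0.00355 with an estimated correlation). On FPKM values 22 also fell, with a median of -1.15. Denervation response genes rose in 13 of 27 cases and fell in 3 (adjusted p = 0.0045, and 0.049 with an estimated correlation). The acetylcholine receptor gene Chrna1 went from 17.1 ± 2.31 to 82 ± 17.5 CPM. Ampd3 stood at 2.08, the transcription factor Runx1 at 1.8 and Fgfbp1 at -5.79. In total 3723 genes rose and 3505 fell, 45.9% of 15760, with 1039 changed by more than 1.

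The scale mattered more in tibialis than elsewhere. FPKM values put the median gene 0.63 higher in R6/2 tibialis against 0.03 with TMM scaling and called 10927 genes higher and 453 lower, and in striatum, heart, liver and cortex the FPKM medians were 0.13, 0.12, 0.11 and 0.1. Oxidative phosphorylation genes fell in 36 of 39 cases (37 when adjusted over the list alone), with Uqcrc1 at -0.94, but their median of -0.49 turned to 0.17 on FPKM values. Their camera adjusted p was 4.05e-16, but 0.319 with an estimated correlation. MEF2 targets of striated muscle fell in 18 of 33 cases and rose in 4 (5 when adjusted over the list alone), but their median of -0.32 turned to 0.34 on FPKM values (adjusted p = 0.000226, but 0.319 with an estimated correlation). The skeletal actin gene Acta1 went from 21600 ± 2380 to 4290 ± 857 CPM, and the glucose transporter gene Slc2a4 stood at -1.21. Clock genes fell in 8 of 19 cases (7 when adjusted over the list alone), with Bhlhe41 at -1.09. Glucocorticoid response genes fell in 9 of 21 and rose in 1 (10 falls when adjusted over the list alone), with Arrdc2 at -2.45 and Sgk1 at -2.41. The medians of clock and glucocorticoid genes, -0.49 and -0.37, turned to 0.27 and 0.23 on FPKM values, and their adjusted p was 0.425 and 0.726 with an estimated correlation. Mitochondrial transcripts took 19.8 ± 1.1% of counts in R6/2 vehicle tibialis and 23.3 ± 1% in wild type.

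In heart, fewer genes changed, and immune genes led the rises. The immunoglobulin gene Ighm (1.81 ± 0.57, adjusted p = 0.0319), the B cell gene Ms4a1 (1.64), Irf4 (1.49), Irf7 (17.7 ± 3.25 against 6.55 ± 1.5 CPM, 1.43 ± 0.17) and Ifit3 (1.34 ± 0.15) rose most under the rule. Acta1 fell from 109 ± 54.8 to 18.8 ± 10.3 CPM (-2.48 ± 0.32, adjusted p = 1.61e-05), ahead of falls that include Ogdhl (-1.26), Foxo6os (-1.05) and Alad (-0.98), an enzyme of haem synthesis. MEF2 targets of striated muscle fell in 17 of 34 cases (18 when adjusted over the list alone; camera adjusted p = 1.09e-11, and 0.00353 with an estimated correlation). The myoglobin gene Mb went from 8620 ± 875 to 6350 ± 484 CPM, and the creatine kinase gene Ckm stood at -0.4. Heat shock genes fell in 7 of 19 cases (10 when adjusted over the list alone), with Hspe1 at -0.37 (adjusted p = 6.96e-07, and 0.0366 with an estimated correlation). In total 1101 genes rose and 1179 fell, 14.4% of 15812, and FPKM values gave 3206 and 260.

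Leukocyte markers rose in 11 of 20 heart cases (18 when adjusted over the list alone; camera adjusted p = 4.71e-08, but 0.12 with an estimated correlation). The antigen presentation gene Cd74 stood at 1.02 ± 0.18, Itgax at 0.99 and Ptprc at 0.9. Oxidative phosphorylation genes fell in 32 of 39 cases (37 when adjusted over the list alone; adjusted p = 3.52e-24, and 0.11 with an estimated correlation). Cox7a1 stood at -0.6 and Uqcrb at -0.42. Cardiac stress and fetal genes fell in 8 of 21 cases, with the natriuretic peptide gene Nppa at -0.72 ± 0.17 (adjusted p = 0.000463, but 0.0638 with an estimated correlation). Atrial markers fell in 5 of 14 cases, with Myl7 at -0.58 and Sln at -0.6 (adjusted p = 0.00123, but 0.413 with an estimated correlation). Red blood cell markers fell in 4 of 8 cases (7 when adjusted over the list alone), with the globin gene Hbb-bs at -0.77 (adjusted p = 7.14e-05, but 0.294 with an estimated correlation). Fibroblast and matrix genes rose in 7 of 20 cases (9 when adjusted over the list alone), with Postn at 0.61 (adjusted p = 0.00167, but 0.48 with an estimated correlation). Immediate early genes fell in 3 of 24 cases and rose in 1, glucocorticoid response genes fell in 2 of 21 and cell cycle genes rose in 2 of 24 (adjusted p = 0.12, 0.578 and 0.671 with an estimated correlation).

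In liver, genes normally higher in female mice rose in R6/2 mice. Genes normally higher in males fell in R6/2 males, while in females 1 of 22 fell and 3 rose, and their list over both sexes had adjusted p = 0.226 with an estimated correlation. Female-biased liver genes rose in 19 of 23 cases with a median of 2.93 (camera adjusted p = 5.4e-21, and 0.0134 with an estimated correlation). A1bg went from 10.3 ± 11.4 to 453 ± 436 CPM (6.13 ± 0.67, adjusted p = 4.12e-07), and Cyp3a41b (6.66 ± 1.13), Cyp3a16 (5.94), Cyp3a41a (4.47) and Cyp2c69 (4.18) were the other large rises. Male-biased liver genes fell in 14 of 22 cases (16 when adjusted over the list alone) with a median of -1.6 (adjusted p = 2.73e-09, but 0.226 with an estimated correlation). Cyp2d9 stood at -2.11. The steepest falls under the rule were Mup1 (-4.9 ± 1.15), Mup9 (-4.45), Cyp4a12a (-3.95), Mup2 (-3.57) and Mup20 (-3.46). The calls of Mup1, Mup2 and Mup9 were lost with library name form as a covariate, and those of Mup2 and Mup9 also with the 2 groups fitted alone. Over the alternatives their adjusted p ran up to 0.0704, 0.112 and 0.0832, from 1.5e-06, 1.03e-05 and 1.66e-06. Cyp3a41a and Cyp3a41b, the Cyp2c genes and the Mup genes are families of near-identical sequence whose reads could not be told apart with certainty here.

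Metabolic and blood cell genes also changed in R6/2 liver. Gluconeogenesis and FOXO target genes fell in 4 of 17 cases (8 when adjusted over the list alone; camera adjusted p = 0.00016, and 0.0237 with an estimated correlation). Pck1, the rate-limiting enzyme of gluconeogenesis, went from 2750 ± 806 to 1560 ± 479 CPM and Tat, a tyrosine aminotransferase, from 1750 ± 688 to 798 ± 178 CPM. Red blood cell markers fell in 5 of 7 cases (7 when adjusted over the list alone; adjusted p = 4.64e-06, and 0.0493 with an estimated correlation). Alas2, an enzyme of haem synthesis, stood at -1.24 and Hbb-bt at -1.16. Leukocyte markers rose in 8 of 20 cases (13 when adjusted over the list alone), with Cd79b at 1.15 and Cd14 at 0.79 (adjusted p = 1.73e-05, but 0.226 with an estimated correlation). Bile acid and transport genes fell in 4 of 16 cases and rose in 1 (9 falls when adjusted over the list alone; adjusted p = 0.171 with an estimated correlation). The sterol transporter gene Abcg8 stood at -0.5 and the bile acid receptor gene Nr1h4 at 0.35. Glucocorticoid response genes fell in 7 of 21 cases and rose in 1, Fkbp5 at 0.87 (8 falls when adjusted over the list alone; adjusted p = 0.454 with an estimated correlation). None of 25 cholesterol synthesis genes passed, at a median of 0.22 (list adjusted p = 0.0095, but 0.856 with an estimated correlation). In total 970 genes rose and 943 fell, 12.8% of 14931, and FPKM values gave 2459 and 321.

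Interferon response genes rose in all tissues. Of 23 listed genes, 22 rose in cortex, 22 in striatum, 23 in tibialis, 23 in heart and 22 in liver, with medians of 1.2, 1.13, 1.27, 0.85 and 1.25 (camera adjusted p from 2.08e-29 to 1.92e-12). With an estimated correlation the adjusted p was 0.0689 in cortex and 0.0385, 0.0364, 0.0263 and 0.0134 in striatum, tibialis, heart and liver. Irf7 rose by 2.28, 2.3, 2.12, 1.43 and 1.7, Ifi44 by 2.23, 2.45, 2.25, 1.32 and 2.19, and Oas1g, a sensor of double-stranded RNA, by 3.15, 3.75, 1.63, 0.9 and 1.82 across the 5 tissues in the same order. With a score of leukocyte markers as a covariate, 10 of the 23 heart calls stayed, against 22 of 22 in cortex. Across 13072 genes tested in all tissues, 62 rose and 12 fell in all 5, against 1.12 and 0.593 expected if the tissues were independent, which they are not since they come from the same mice. Besides these, Gm12695, Ifi27l2a, Ifi213, Ifit1, Usp18, Oas1a and Oasl2 had the largest mean rises. The total of 74 was 139 without the libraries of few long transcripts and 301 on FPKM values. Of 4414 genes called in both cortex and striatum, 2559 rose and 1755 fell in both (1040 and 529 expected), and of 1220 in tibialis and heart, 421 and 691 (231 and 241). Of 1146 in cortex and heart only 300 and 214 did so (300 and 238), and of 812 in striatum and heart 226 and 130 (234 and 186). More than 50% of these changed in opposite directions. The number to be had so if the tissues were independent was not computed, so an excess of opposite changes was not tested.

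**Figure D2:**
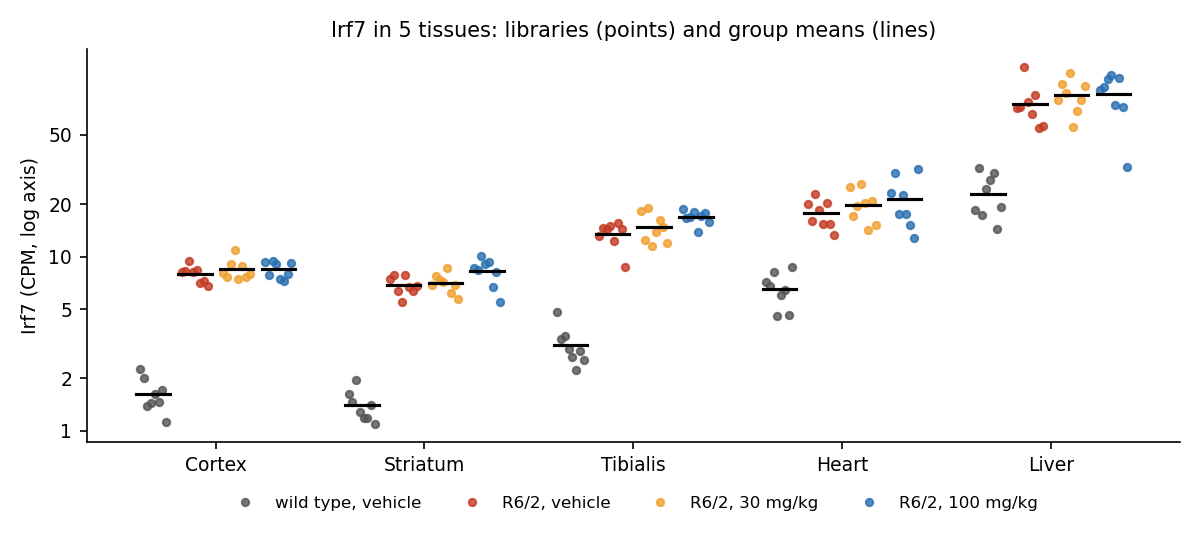
Irf7 in CPM on a log axis for each tissue and arm, with 1 point per library and lines at the means of 8 mice. R6/2 vehicle means stand above wild type in each tissue, from 6.85 against 1.4 CPM in striatum to 75.4 against 22.9 CPM in liver, and the treated arms lie near the vehicle arm.

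The sexes differed in the response of the liver to the genotype. Cyp2b9, a cytochrome higher in females, stood at 15.4 ± 7.53 CPM in wild-type males, 564 ± 183 in wild-type females, 735 ± 87.6 in R6/2 males and 476 ± 25.2 in R6/2 females (n = 4 each). The male effect exceeded the female effect by 5.82 ± 0.33 (adjusted p = 1.39e-12). Cyp2b13 (8.44 ± 0.48) and Cyp2a22 (5.06 ± 0.5) followed. Male-biased genes fell in R6/2 males in 19 of 22 cases with a median of -3.06, and in females 1 fell and 3 rose, with 17 past the test of the sex difference. Female-biased genes rose in 20 of 23 cases in males with a median of 6.35 and in 9 of 23 in females with a median of 1.55, with 11 past the test of the sex difference. The listed genes that differed between the sexes went from 18 of the male-biased and 18 of the female-biased in wild type to 1 and 3 in R6/2 vehicle. The median difference of males from females went from 2.76 to -0.27 for the male-biased and from -5.14 to -1.24 for the female-biased genes, so a part of the latter difference stayed. Without vehicle female 4 alone, a library of few long transcripts, the R6/2 counts were 0 and 3 and the medians -0.13 and -1.21. In liver 130 genes had a more positive and 137 a more negative effect in males, while DESeq2 gave 481 in total.

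**Figure D3:**
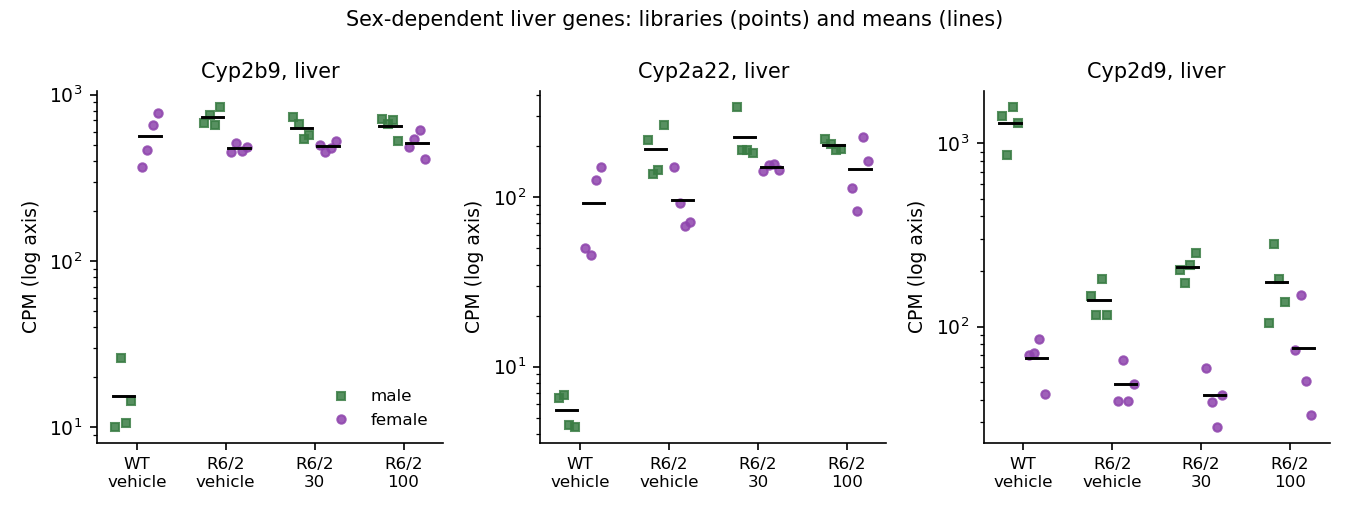
Liver CPM on a log axis for Cyp2b9, Cyp2a22 and Cyp2d9 by arm, with squares for males and circles for females (n = 4 per sex and arm). Cyp2d9 stands at 1290 CPM in wild-type males and 67.5 in females, and at 140 and 48.4 CPM in R6/2 vehicle males and females.

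Outside the liver, the sex difference in the genotype effect reached 8 genes in tibialis and 1 in heart. Amd1, an enzyme of polyamine synthesis, fell by 2.25 in males against -0.22 in females (difference -2.03 ± 0.17, adjusted p = 6.32e-08), and Smox, which oxidises spermine, stood at -3.48 and -1.8 (difference -1.69 ± 0.25). Spns2 followed at a difference of -0.85 ± 0.13. In heart, Fbp2, a fructose bisphosphatase, stood at -0.62 in males and 0.32 in females (-0.95 ± 0.16, adjusted p = 0.0248). The tibialis count ranged from 4 without the filter on low counts to 60 without the libraries of few long transcripts, and was 51 by DESeq2 and 38 on FPKM values. The heart count was 16 by DESeq2 and 2 without the libraries of few long transcripts. In heart 4 of 100 sets with permuted residuals gave as many genes by limma. No gene passed by edgeR in cortex or striatum, where 1129 and 1090 had an unadjusted p under 0.05 against 875 and 871 to be had by chance. DESeq2 gave 12 and 3 there and limma on FPKM gave 0 in both.

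Genes for class IIa deacetylases and their MEF2 partners showed small changes with genotype. Hdac7 and Hdac4 fell in R6/2 cortex (-0.31 ± 0.06 and -0.16 ± 0.05), and Hdac5 fell in striatum (-0.46 ± 0.1). Mef2d, a transcription factor that class IIa deacetylases repress, fell in cortex (-0.3 ± 0.04), striatum (-0.37 ± 0.1) and tibialis (-0.47 ± 0.06), where FPKM values turned it to a rise of 0.22 (adjusted p = 0.0201, the highest over 7 alternatives, which started at 1.12e-16). Mef2c fell in cortex (-0.23 ± 0.06). On FPKM values the calls of Hdac4 and Mef2c in cortex and of Hdac5 and Mef2d in striatum were lost (adjusted p = 0.0595, 0.0502, 0.482 and 0.106). These were the highest values over their alternatives, which started at 0.000611, 0.000588, 1.88e-05 and 1.16e-07. Of 17 genes for deacetylases and MEF2 factors, 5 rose and 7 fell in cortex, 4 and 4 in striatum, 3 and 3 in tibialis and 0 in heart and liver, with camera adjusted p from 0.566 to 0.899. At 30 and 100 mg/kg no gene among Hdac4, Hdac5, Hdac7, Hdac9, Mef2a, Mef2c and Mef2d passed in any tissue, Mef2d (0.22 ± 0.07, adjusted p = 0.0826) and Hdac5 (0.43 ± 0.13, adjusted p = 0.0868) in liver at 100 mg/kg coming closest.

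At 100 mg/kg, genes of xenobiotic metabolism rose in the liver of R6/2 mice. Genes of PPARalpha and of the heat shock response rose too, but their lists did not hold with an estimated correlation (adjusted p = 0.112 and 0.16). Cyp2c29, a drug-metabolising cytochrome, rose from 2830 ± 621 to 6160 ± 1180 CPM (1.13 ± 0.14, adjusted p = 2.7e-05). Ehhadh, an enzyme of peroxisomal fatty acid oxidation, rose from 427 ± 96.8 to 1130 ± 295 CPM (1.41 ± 0.16, adjusted p = 8.76e-06). For both, all 8 treated mice stood above all 8 vehicle mice. The largest rises under the rule were Cyp4a12a (3.46 ± 0.84), the glutathione transferase genes Gsta1 (3 ± 0.53) and Gstm3 (545 ± 347 against 103 ± 29.4 CPM, 2.39 ± 0.33), Cyp2c55 (2.17 ± 0.31) and the lipoprotein lipase gene Lpl (92.3 ± 93.5 against 22.2 ± 6.66 CPM, 2.05 ± 0.36). The steepest falls under it were Ntrk2 (-2.09 ± 0.47), a neurotrophin receptor, Clec2h (-1.63), Enho (-1.32), the interferon regulator Irf5 (6.79 ± 1.92 against 16 ± 3.46 CPM, -1.26 ± 0.17) and Bmf (-1.18 ± 0.31), which promotes cell death. In total 207 genes rose and 101 fell, with a median size of 0.51, and DESeq2 gave 602 and limma on FPKM 251 and 62, while edgeR gave 165 with the 2 groups alone and 176 without the filter. Cyp4a12a lost its call on FPKM values, with the replicate block and with the 2 groups alone, where it stood at 2.58, 2.74 and 3.17. Bmf, Enho and Clec2h lost theirs without the libraries of few long transcripts, where they stood at -1.13, -1.25 and -1.36, among other settings. Over 8 alternatives the adjusted p of these 4 genes ran up to 0.11, 0.0962, 0.0619 and 0.102, from 0.000745, 0.00646, 0.00275 and 0.00908.

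Xenobiotic metabolism genes rose in 15 of 38 liver cases (25 when adjusted over the list alone) with a median of 0.49, Gstm1 standing at 1.15 ± 0.17. Of the lists tested at 100 mg/kg in the 5 tissues, this one alone held with an estimated correlation (camera adjusted p = 2.67e-19, and 0.0334 with an estimated correlation). PPARalpha target genes rose in 8 of 24 cases (13 rises and 1 fall when adjusted over the list alone; adjusted p = 7.59e-13, but 0.112 with an estimated correlation). The fatty acid hydroxylase gene Cyp4a14 went from 970 ± 217 to 2650 ± 677 CPM, the thiolase gene Acaa1b from 673 ± 134 to 1470 ± 390 CPM, and Cpt1b stood at 1.05 ± 0.2. Heat shock genes rose in 5 of 19 cases (7 when adjusted over the list alone; adjusted p = 1.86e-06, but 0.16 with an estimated correlation). The chaperone gene Hspb1 stood at 1.02 ± 0.21 and Hsp90aa1 at 0.76 ± 0.12. Lipogenesis genes rose in 2 of 20 cases, Me1 at 0.75 and Mlxipl at 0.35 (adjusted p = 0.0177, but 0.67 with an estimated correlation). Acute phase genes fell in 2 of 24 cases, the iron hormone gene Hamp at -1.1 ± 0.28 and Itih4 at -0.52 ± 0.13 (adjusted p = 0.000104, but 0.455 with an estimated correlation). Among clock genes 1 of 19 fell, Hlf at -0.44 ± 0.11 (2 rises and 10 falls when adjusted over the list alone), with adjusted p = 0.16 for the list with an estimated correlation. The calls of Me1, Mlxipl, Hamp, Itih4 and Hlf were lost without the libraries of few long transcripts, while their changes stayed about as large (0.76, 0.32, -1.04, -0.49 and -0.42). Over 8 alternatives their adjusted p ran up to 0.0936, 0.108, 0.0914, 0.0582 and 0.175, from 0.00704, 0.00994, 0.0185, 0.003 and 0.00979. Female-biased liver genes fell in 1 of 23 cases, and of endothelial, cholesterol synthesis, p53 target and interferon response genes none passed, although each list passed camera (adjusted p from 0.391 to 0.67 with an estimated correlation).

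**Figure D4:**
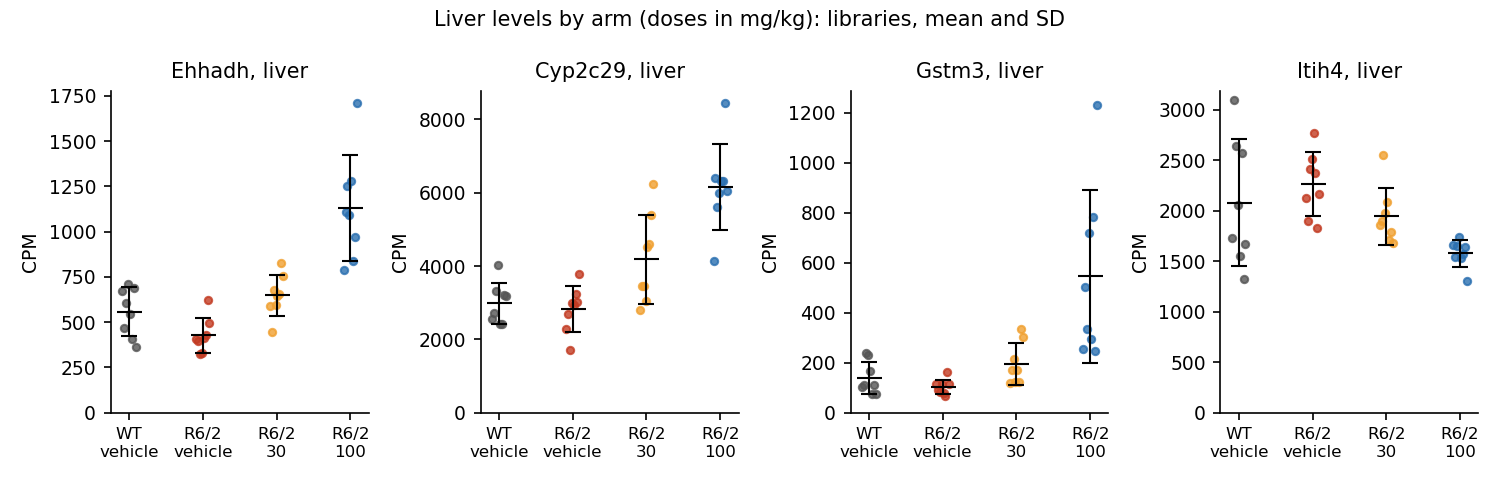
Liver CPM of Ehhadh, Cyp2c29, Gstm3 and Itih4 in wild type and in R6/2 mice on vehicle, 30 and 100 mg/kg, with 1 point per mouse and the mean ± SD of 8 mice. Ehhadh goes from 427 through 648 to 1130 CPM and Itih4 from 2260 through 1940 to 1580 CPM with dose.

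In the other tissues, 100 mg/kg left few calls. In heart, Manf, a secreted protein of the unfolded protein response, rose from 18.4 ± 2.45 to 29.2 ± 6.26 CPM (0.67 ± 0.11, adjusted p = 0.0084). Ighd, an immunoglobulin gene, fell from 5.23 ± 2.48 to 1.84 ± 0.761 CPM (-1.44 ± 0.26, adjusted p = 0.0286). Both calls were lost on FPKM values and with the 2 groups alone, where 2 other genes passed, and that of Ighd without the libraries of few long transcripts. The changes stayed about as large, for Manf at 0.62 on FPKM values and 0.67 with the 2 groups alone. Ighd stood at -1.4 and -1.38 there and at -1.31 without those libraries. Over 7 alternatives the adjusted p ran from 7.86e-06 to 0.101 for Manf and from 7.35e-05 to 0.167 for Ighd. In cortex only Tmem252 rose, from 1.53 ± 0.437 to 2.54 ± 0.375 CPM (0.73 ± 0.13, adjusted p = 0.0466). Its call was lost without the filter on low counts, with the 2 groups alone, without the libraries of few long transcripts and with library name form as a covariate. There its change stayed about as large (0.74, 0.74, 0.66 and 0.72). Over 9 alternatives its adjusted p ran from 0.000504 to 0.657, and 2 of 40 splits of the mice gave as many genes. By edgeR 0 genes passed in striatum, where 680 had an unadjusted p under 0.05 against 871 to be had by chance. DESeq2 and limma on FPKM also gave 0 there, and 3 of the 8 treated libraries had few long transcripts. In tibialis 0 passed as well, where 2164 had an unadjusted p under 0.05 against 788 to be had by chance. DESeq2 gave 6 there and limma on FPKM 3. DESeq2 gave 15 in cortex and 60 in heart, and limma on FPKM 1 and 0, while edgeR gave 8 in heart with RLE scaling and 11 with the replicate block. The gene with the smallest p was Atcayos in striatum (-0.43 ± 0.1, adjusted p = 0.998) and Rsc1a1, a regulator of glucose transport, in tibialis (-0.95 ± 0.19, adjusted p = 0.168).

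Camera with its preset correlation passed many lists at both doses, also where no gene was called. At 100 mg/kg these were 7 of 26 in cortex, 9 of 26 in striatum, 11 of 25 in tibialis, 11 of 25 in heart and 11 of 26 in liver, and at 30 mg/kg 6, 11, 4, 4 and 10. With an estimated correlation 1 passed in liver at 100 mg/kg and 0 elsewhere. Among those that leaned at 100 mg/kg without single calls, a few are given here. All 39 oxidative phosphorylation genes of tibialis had positive values with a median of 0.19, and 0 passed (camera adjusted p = 1.42e-15, but 0.536 with an estimated correlation). Among 20 leukocyte markers of heart, 19 had negative values with a median of -0.38, and 0 passed (6 when adjusted over the list alone; list adjusted p = 2.32e-07, but 0.379 with an estimated correlation). The B cell gene Cd79b came closest, at -1.7 with adjusted p = 0.0524. The 17 genes for deacetylases and MEF2 factors had a median of -0.08 in tibialis, where 0 passed (3 when adjusted over the list alone; list adjusted p = 0.0205, but 0.554 with an estimated correlation). Genes known to respond to broad deacetylase inhibitors had a median of 0.07 in heart, where 0 passed (2 when adjusted over the list alone; list adjusted p = 0.0357, but 0.379 with an estimated correlation). The sex difference in the 100 mg/kg effect reached 1 gene, Igfn1, a muscle protein gene, in tibialis (-2.25 ± 0.39, adjusted p = 0.049), but not with RLE scaling, on FPKM values or without the libraries of few long transcripts. Limma on log2 CPM gave 0 here. For cortex, striatum, heart and liver edgeR gave 0, with 376, 422, 577 and 2772 genes at an unadjusted p under 0.05. By chance 875, 871, 791 and 747 were to be had, and among these tissues only the liver count was higher. DESeq2 gave 1, 0, 3 and 107 in them and limma on FPKM 0 in each. In tibialis 1904 genes had an unadjusted p under 0.05 against 788 to be had by chance. Genes vary together, so a count above that number does not exclude chance.

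At 30 mg/kg no gene passed in any tissue by the main edgeR fit, and 1 passed in liver with RLE scaling. The smallest adjusted p was that of the chromatin protein gene Hp1bp3 in liver (0.33 ± 0.06, adjusted p = 0.0753), and Col1a1, a collagen gene, came closest in cortex (0.68 ± 0.14, adjusted p = 0.419). The smallest p in striatum, tibialis and heart was that of Cdc6 (0.72 ± 0.17), Pop4 (0.43 ± 0.1) and Cnr2 (-0.86 ± 0.19), with adjusted p = 0.745, 0.96 and 1. Unadjusted p under 0.05 was reached by 818 genes in cortex, 843 in striatum, 631 in tibialis, 612 in heart and 1097 in liver, with 875, 871, 788, 791 and 747 to be had by chance. DESeq2 called 1, 0, 0, 0 and 1 genes and limma on FPKM 0 in each. In liver, Ehhadh stood at 648 ± 115 CPM (0.6 ± 0.16, adjusted p = 0.6) and Cyp2c29 at 4180 ± 1210 CPM (0.55 ± 0.14, adjusted p = 0.6). Xenobiotic genes of liver passed camera at 30 mg/kg with 0 single calls (6 when adjusted over the list alone; adjusted p = 1.65e-09, but 0.474 with an estimated correlation), as did PPARalpha targets (3 when adjusted over the list alone; 0.49 with an estimated correlation).

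Set directly against 30 mg/kg, 100 mg/kg lowered 1 liver gene by edgeR, Sprn (0.41 ± 0.14 against 1.02 ± 0.384 CPM, -1.28 ± 0.21, adjusted p = 0.0161), named after its values were seen. With the 2 groups alone and on FPKM values this count was 0, and DESeq2 gave 37. For cortex, striatum, tibialis and heart edgeR gave 0, with 1181, 2305, 1177 and 893 genes at an unadjusted p under 0.05. By chance 875, 871, 788 and 791 were to be had. DESeq2 gave 3, 0, 1 and 3 and limma on FPKM 0 in each. In these tissues 2, 3, 1 and 1 of the 8 libraries at 100 mg/kg had few long transcripts and 0 at 30 mg/kg. Counts above those to be had by chance can therefore not be ascribed to dose alone. The effects of the 2 doses share their vehicle mice, so their covariance over genes was taken with the vehicle mice split between the doses. In liver it was 0.0172 ± 0.00742 (SD over 36 splits) against 0.00092 in simulated data without a drug effect, and in cortex, striatum, tibialis and heart it was -0.00459 ± 0.00509, -0.0359 ± 0.0325, -0.0153 ± 0.0125 and -0.000456 ± 0.00546 against 0.0014, 0.00229, 0.00194 and 0.00173 in simulated data. Without the filter on low counts, where no simulation was run, it was 0.00466 ± 0.00535 in cortex, -0.0677 ± 0.0616 in striatum, -0.0447 ± 0.0267 in tibialis, -0.00549 ± 0.0127 in heart and 0.0285 ± 0.0181 in liver. All splits reuse the same mice, so their SD does not measure the error between mice. The simulated values are means over 20 data sets with 1 split each, not 36. Simulated genes varied independently, unlike real ones, so the simulated values do not test the liver covariance.

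Neither dose shifted the R6/2 signature as a whole past the test. On an index where wild type is 0 and the R6/2 profile 1, vehicle mice stood at 0.981 ± 0.027 in cortex, 0.98 ± 0.051 in striatum, 0.985 ± 0.072 in tibialis, 0.794 ± 0.187 in heart and 0.915 ± 0.198 in liver (mean ± SD). At 100 mg/kg the difference from vehicle was 0.007 ± 0.013 in cortex, 0.009 ± 0.031 in striatum, -0.015 ± 0.036 in tibialis, -0.137 ± 0.084 in heart and -0.08 ± 0.108 in liver. At 30 mg/kg it was 0.005 ± 0.016, -0.033 ± 0.029, -0.023 ± 0.03, -0.127 ± 0.08 and 0.017 ± 0.088 in the same order. Differences are given ± SE with the sexes pooled. The SE thus includes the spread between the sexes, which the permutation within sex leaves out. The smallest exact permutation p was 0.0498 in striatum at 30 mg/kg, and adjusted over the 10 two-sided tests the values ran from 0.476 to 0.758.

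**Figure D5:**
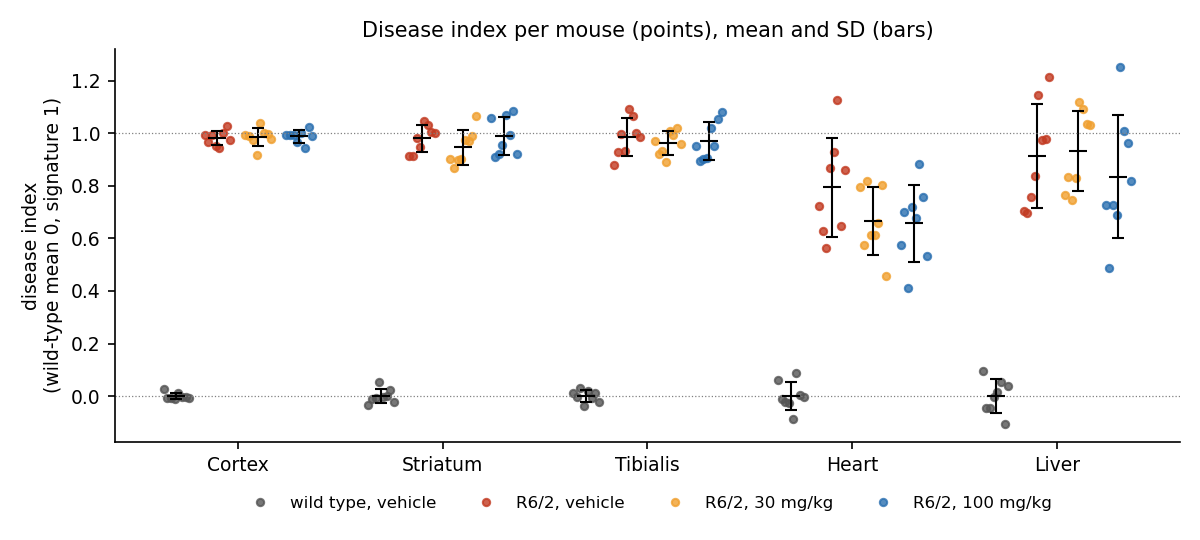
Disease index (0 for wild type, 1 for the R6/2 profile, no unit) per mouse for each tissue and arm, with 1 point per mouse and the mean ± SD of 8 mice. The treated means lie within 0.137 of the vehicle means, which run from 0.794 in heart to 0.985 in tibialis.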

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

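The tests on the libraries of contradicting sex, the fits without libraries of few long transcripts and with the name form, the leukocyte test taken over 4 tissues, the even splits and the permuted residuals were chosen only after the results were seen; the other tests in this part were planned or written down before.

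Xist and Ddx3y, which mark sex, contradicted the label in the wild-type cortex library of female 3 and the striatum library of female 2, both from 1 mouse whose tibialis, heart and liver libraries are female. Xist stood at 0.265 and 1.78 CPM against 821 to 1390 and 533 to 1300 CPM in the other females, and Ddx3y at 69.3 and 64.1 CPM against 62.1 to 90.6 and 47.6 to 108 CPM in males. A swap within the tissue is argued against, since 0 libraries labelled male had more Xist than Ddx3y, and a mixture is too, since Xist reached at most 0.147% of the median of the other females. RNA from a male mouse may be the source, as 7 of 8 values of Y-linked genes lay in the male range. The criterion written for this source asked for all 8 in that range, so it was not met. The other value, Uty in cortex at 17.3 CPM, lies 1.82 SD from the male mean. A range set by 16 male libraries may be too narrow a bound. Xist too lay outside the male range, below 0.412 to 1.72 CPM in cortex and above 0.34 to 1.57 CPM in striatum. Its distances from the male mean were -1.29 and 2.29 SD. Without both libraries Ddx3y went from -2.83 ± 1.02 to 0.2 in cortex and from -4.05 ± 1.25 to 0.28 in striatum, and over its alternatives the adjusted p ran from 0.00154 to 0.287 and from 0.00951 to 0.431.

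Interferon response genes rose in R6/2 mice in all 5 tissues. More leukocytes could account for part of this in heart, where the leukocyte score was 0.71 higher in R6/2 and only 10 of 23 calls (43.5%) stayed with that score as a covariate (median from 0.85 to 0.69), the score and the arm competing for the same differences. In cortex, striatum, tibialis and liver leukocytes as the whole cause are argued against, since at least 72.7% of the calls stayed and the cortex score differed by 0. A chromosome segment linked to the transgene that itself holds most of these genes is argued against by the known positions of the genes. Of the 22 members that rose everywhere, 9.1% lie on the chromosome of Gm12695. Nearly all listed genes rose everywhere, so this share was largely set by the make-up of the list. That share cannot see a linked gene that acts on genes elsewhere, so such an effect stays open. The libraries of few long transcripts are argued against too, since 100% of the calls stayed without them. A biological response to the genotype remains a hypothesis, found and tested on the same mice, and in heart a change in cell composition stays open.

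In liver, 207 genes rose and 101 fell at 100 mg/kg. The libraries of few long transcripts, as the whole cause, are argued against, since 185 of the 308 genes were still called without them, and so is a library batch seen in the name form, with 190 still called. A trend with transcript length and GC content is argued against too, since the fitted trend had an SD of 0.033 across genes against a median change of 0.51 in the called ones, and 305 kept at least 50% of their change once it was removed. A response of the liver to the drug remains a hypothesis, because the drug was given to R6/2 mice alone and the time between last dose and collection is not given in the sources used here.

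Single libraries stood apart from their group of 8 in 12 of 70 groups of values, and chance gives about 1 in 20. Library totals stood apart for cortex vehicle male 2 at 35.5 M counts (next 33.9), cortex 100 mg/kg female 4 at 30.3 (next 32.9), striatum wild-type female 4 at 38.9 (next 32.5), tibialis vehicle male 4 at 39 (next 36) and liver 30 mg/kg male 2 at 37.2 (next 34.6). Gm12695 stood at 4.5 CPM in cortex 100 mg/kg male 2 (next 3.49), 0.769 CPM in striatum vehicle male 2 (next 3.58) and 0.58 CPM in heart 100 mg/kg male 4 (next 1.58). Htt stood at 78.4 CPM in striatum vehicle male 2 (next 182), 10.5 CPM in tibialis 100 mg/kg male 1 (next 23), 15.8 CPM in tibialis wild-type female 4 (next 23.5) and 28.4 CPM in heart wild-type male 4 (next 33). The last 4 of these libraries, heart 100 mg/kg male 4 and cortex vehicle male 2 are among those of few long transcripts.

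Effects differed between males and females in tests of the difference itself. The genotype effect differed for 8 genes in tibialis, among them Amd1 (-2.03), Smox (-1.69) and Spns2 (-0.85). It differed for 1 gene in heart, Fbp2 (-0.95), and for 267 genes in liver, led by Cyp2b9 (5.82), Cyp2b13 (8.44) and Cyp2a22 (5.06). The 100 mg/kg effect differed for 1 gene in tibialis, Igfn1 (-2.25). That call was lost with RLE scaling (-2.22), on FPKM values (-1.57) and without the libraries of few long transcripts (-2.22).

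Mice were also regrouped within sex, with 40 splits per result, the real one among them. With 40 splits, 1 of 40 is the smallest share that can be reached. For R6/2 against wild type chance is argued against in every tissue, with 1 of 40 splits as large in each. The real counts were 9439, 7388, 7228, 2280 and 1913 genes in cortex, striatum, tibialis, heart and liver. Their highest other counts were 179, 54, 0, 23 and 193 in the same order. Chance is also argued against for 100 mg/kg in liver (308, 1 of 40 as large, highest other 1). For 100 mg/kg in heart (2 genes, highest other 0) and 100 against 30 mg/kg in liver (1, highest other 0) only the real split was as large. These counts are small, and many results were tested this way. The genes also lost their calls with the 2 groups alone, where 2 other genes passed in heart and 0 in liver. Their changes there stayed about as large, at 0.67 for Manf, -1.38 for Ighd and -1.28 for Sprn. Chance is not excluded for these results. Nor is it for 100 mg/kg in cortex (1 gene, 2 of 40 splits as large, highest other 64). Results of 0 genes are reached by all 40 splits by construction, so chance cannot be excluded for them. Their highest other counts were 2, 0, 0, 0 and 0 at 30 mg/kg, 5700 in striatum and 109 in tibialis at 100 mg/kg, and 1, 0, 0 and 0 for 100 against 30 mg/kg in cortex, striatum, tibialis and heart. The counts in striatum at 100 mg/kg point to a structure of the samples. The 5 splits that put all 4 libraries of few long transcripts on 1 side gave 2913 to 5700 genes, and the other splits at most 1.

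For the sex differences, splits of this kind do not test chance. A split that keeps the groups apart in 1 sex and mixes them in the other turns the effect of the genotype itself into a difference between the sexes. Such counts were 4461 in tibialis (3 of 40 splits as large as the real 8), 674 in heart (3 of 40, real 1), 668 in liver (3 of 40, real 267), 1858 in cortex and 1 in striatum (real 0). For the 100 mg/kg effect the highest other counts were 6 in tibialis (4 of 40, real 1) and 4, 5555, 2 and 38 in cortex, striatum, heart and liver (real 0). Splits with as many mice on their own side in males as in females leave that effect out, but it then widens the spread within their groups and lowers their counts, so these do not test chance either. With 40 such even splits the genotype effect gave 267 in liver (1 of 40 as large, highest other 0), 8 in tibialis (1 of 40, highest other 2), 1 in heart (2 of 40, highest other 1) and 0 in cortex and striatum (highest other 0). The 100 mg/kg effect gave 1 in tibialis (5 of 40, highest other 90) and 0 in cortex, striatum, heart and liver (highest other 2, 4414, 71 and 1). Another test kept the effects of group and sex in place and permuted the residuals of a fit without their interaction, with limma on log2 CPM and 100 sets including the real one. Here chance is argued against for the genotype effect in liver (119 genes by limma, 1 of 100 as large, highest other 13) and tibialis (11, 1 of 100, highest other 3). A share of 1 of 100 is the smallest that can be reached. For 1 gene in heart, 4 of 100 were as large and the highest other was 7, which for a single gene among 10 such tests does not exclude chance, and nor is it excluded for the 100 mg/kg effect in liver (1, 6 of 100, highest other 25). The other results were 0 by limma, which all 100 sets reach, with highest others of 9 and 2 in cortex and striatum for the genotype and 1006, 6484, 7 and 106 in cortex, striatum, tibialis and heart for 100 mg/kg. The 5555 and 4414 genes in striatum came from the splits that set the 3 male libraries of few long transcripts against the female one, a structure of the samples.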

How the results depend on the processing

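The comparisons, the model, the gene lists, the rule for named genes and the alternatives other than the leaving out of libraries and the name form were fixed before the data were examined; those were chosen after seeing the data. The counts for R6/2 against wild type stayed within 1.5 times in every tissue except on FPKM values for tibialis (11380) and heart (3466). Of the counts, covariances and index values compared, 35 of 38 stayed with RLE scaling, 28 of 35 without the filter, 13 of 32 with DESeq2, 24 of 32 on FPKM values, 19 of 20 with the replicate block and 17 of 20 with the 2 groups alone. The same held for 33 of 42 without the libraries of few long transcripts, 16 of 16 without the libraries of contradicting sex and 10 of 12 with the name form, and the rest are given here. Unless fewer samples or genes account for it, the cause was not tested. Among named genes, direction and call stayed in 287 of 288 comparisons with RLE scaling, 280 of 288 without the filter, 286 of 286 with DESeq2, 251 of 279 on FPKM values, 275 of 280 with the block and 260 of 280 with the 2 groups alone. They also stayed in 276 of 288 without the libraries of few long transcripts, 124 of 126 without those of contradicting sex and 126 of 137 with the name form.

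With DESeq2, 30 mg/kg gave 1 gene in cortex and 1 in liver, and 100 mg/kg gave 15 in cortex, 6 in tibialis, 60 in heart and 602 in liver. By the same tool 100 against 30 mg/kg gave 3 in cortex, 1 in tibialis, 3 in heart and 37 in liver. The sex difference in the genotype effect then gave 12, 3, 51, 16 and 481 genes in cortex, striatum, tibialis, heart and liver, and that in the 100 mg/kg effect 1, 10, 3 and 107 in cortex, tibialis, heart and liver. Without the filter on low counts, 100 mg/kg gave 0 genes in cortex and 176 in liver, the sex differences gave 4 for the genotype in tibialis and 1 for 100 mg/kg in liver, and the dose covariance was 0.00466 in cortex, -0.0447 in tibialis and 0.0285 in liver. RLE scaling gave 8 genes in heart at 100 mg/kg, 0 for the sex difference at 100 mg/kg in tibialis and 1 in liver at 30 mg/kg. Limma on FPKM values gave 3 genes in tibialis and 0 in heart at 100 mg/kg, 38 and 0 for the sex differences in tibialis (genotype, 100 mg/kg), 0 for 100 against 30 mg/kg in liver and 301 genes changed alike in all 5 tissues.

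The 2 groups alone, with fewer samples, gave 0 genes at 100 mg/kg in cortex, 165 in liver and 0 for 100 against 30 mg/kg in liver. The replicate number as a block gave 11 genes at 100 mg/kg in heart; these numbers mark different animals, and across genes, libraries with the same number had a mean r of 0.082 in heart and 0.069 in liver against -0.027 and -0.023 for other numbers. There 18 and 16 of 32 libraries correlated best with their own number, a hint from the data and not the design, against 8, 12 and 4 in cortex, striatum and tibialis and 8 by chance. Without the libraries of few long transcripts, 100 mg/kg gave 0 genes in cortex and 1 in heart, 100 against 30 mg/kg gave 2 in liver, the sex differences gave 60 (tibialis) and 2 (heart) for the genotype and 0 for 100 mg/kg in tibialis, and 139 genes changed alike in all 5 tissues. The name form as a covariate gave 0 genes at 100 mg/kg in cortex and 1 for the sex difference at 100 mg/kg in liver. Of the gene lists past camera, 20 held with an estimated correlation.

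Index differences, none past the test, changed sign in cortex at 100 mg/kg with 100 genes (-0.003) and on FPKM values (-0.006), in liver at 30 mg/kg with 1000 genes (-0.001) and without the libraries of few long transcripts (-0.02), and in striatum at 100 mg/kg without those libraries (-0.032). Ddx3y turned to 0.2 in cortex and 0.28 in striatum without the libraries of contradicting sex. On FPKM values tibialis Mef2d turned to 0.22, Atp5a1 to 0.07 and Nr1d1 to 0.06. At these depths the self-test recovered 63% to 88% of simulated changes of 0.5 and 89% to 99% of changes of 1 across the tissues. Its changed genes had a mean log2 CPM of at least 1, so recovery among lower genes was not measured. Recovery was not compared between levels of expression either.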

Other observations

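The clock test, the other fits of the counts per sex and the look at the genes nearest the insertion were chosen only after the results were seen. The tests on genes within 5 Mb of the insertion and on the median span of long genes were written down before.

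Counts of sex-biased genes in the liver were taken with each arm's 4 males set against its 4 females. In wild type 163 genes were higher in males and 203 in females. In R6/2 vehicle these counts were 25 and 49, at 30 mg/kg 184 and 672, and at 100 mg/kg 21 and 24. At 30 mg/kg all 4 male libraries carry the second name form and all 4 female libraries the first, so sex and a library batch cannot be told apart in this arm. With the name form as a covariate, fitted over all arms, its counts were 85 and 291. The vehicle, 30 and 100 mg/kg arms each hold 1 library of few long transcripts, with length slopes of -0.33, -0.12 and -0.25, and without the libraries of few long transcripts the counts were 228 and 294 in wild type, 15 and 20 on vehicle, 170 and 408 at 30 mg/kg and 12 and 9 at 100 mg/kg. Without vehicle female 4 alone they were 13 and 21 on vehicle and 48 and 43 at 100 mg/kg. The differences between these counts were not tested. Within each sex alone, with 4 mice per arm, R6/2 against wild type gave 7329 genes in males and 6732 in females in cortex, 5687 and 3912 in striatum, 5683 and 4904 in tibialis, 1348 and 93 in heart and 1509 and 797 in liver. The wild-type females of cortex and striatum each include 1 library with a male pattern of sex genes, and without these 2 libraries, with 3 wild-type females left, the counts were 7310 and 6267 in cortex and 5617 and 3415 in striatum. At 100 mg/kg 137 liver genes passed in males and 243 in females. In heart 6 and 1 did so, in tibialis 2 and 0, and in cortex and striatum 0 in both sexes. Counts per sex do not test a difference between the sexes. The tests of the difference itself gave 0, 0, 8, 1 and 267 genes for the genotype in cortex, striatum, tibialis, heart and liver. For 100 mg/kg they gave 1 gene in tibialis and 0 in the other tissues.

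Clock genes leaned alike across the peripheral tissues of the mice at 100 mg/kg. Dbp, an output gene of the clock, stood at -0.82 ± 0.24 in tibialis and -1.66 ± 0.63 in liver, and Npas2, which works at the opposite phase, at 1.04 ± 0.31 and 3.25 ± 0.96, none past the test (adjusted p = 0.299, 0.166, 0.299 and 0.0693). A score of 8 genes of the Dbp phase minus 3 of the Npas2 phase, averaged over tibialis, heart and liver, was -0.65 ± 0.88 (SD) at 100 mg/kg and 0.4 ± 0.35 on vehicle, with 6 of 8 treated mice under the vehicle mean (exact permutation p = 0.00612, two-sided, adjusted over 12 tests 0.0261). The difference was -1.02 in tibialis (adjusted 0.0196), -0.98 in heart (0.0518), -1.14 in liver (0.0261), -0.28 in striatum (0.0477) and -0.1 in cortex (0.502), and over the 3 peripheral tissues at 30 mg/kg it was -0.37 (0.225). Wild-type mice ranged widely (0.23 ± 1.04). The genes and tissues of the score were chosen once the lean had been seen, so these p values test neither a shift of clock phase nor its absence, and the hour of collection is not given in the sources used here.

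Genes near the transgene insertion were compared with all genes. Within 5 Mb of Gm12695, 19 of 43 genes tested in cortex passed (44.2%) against 53.9% of all genes, a ratio of 0.82. The ratio was 0.91 in striatum, 1.09 in tibialis, 1.18 in heart and 0.37 in liver, all under the bound of 1.5 set beforehand, and the differences were not tested. A share over 5 Mb cannot see an effect on the nearest genes alone. Cyp2j6, 208 kb away, rose in cortex, striatum, tibialis and heart (0.17 ± 0.04, 0.24 ± 0.05, 0.26 ± 0.06 and 0.16 ± 0.06), and Cyp2j9, 155 kb away, fell in cortex and striatum (-0.36 and -0.31) and rose in heart (0.33). Reads of these related genes could not be told apart with certainty here, and a local effect of the insertion stays open.

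Whether long genes fell selectively in the brain stays open. Genes that fell in cortex had a median span of 34.8 kb and those that rose 23.6 kb, a ratio of 1.48, and striatum gave 34.1 and 23.1 kb, also 1.48. Without the libraries of few long transcripts the ratios were 1.33 and 1.04, under the bound of 1.5 set beforehand. All these cortex and striatum ratios fell short of it, so the prediction written beforehand failed. Medians can miss the longest genes, and the counts over 100 kb that follow were not part of that prediction. Of genes over 100 kb, 840 fell and 470 rose in cortex (860 and 503 without those libraries) and 622 fell and 319 rose in striatum (738 and 570), although among all genes compared more rose than fell (4207 and 3478 in cortex, 3191 and 2714 in striatum). The ratio was 0.56 in tibialis, 0.31 in heart and 1.84 in liver, in the last 1.34 without those libraries.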
